A study of Homo sapiens with 12 samples.

How the data were processed

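RNA was measured in 12 samples of U87, a human glioblastoma cell line, in 4 groups of 3: cells with an empty plasmid or with a plasmid for DPF3, each without drugs or after 48 h with 0.5 mM 8-cpt-cAMP and 1 nM MS275. The groups and replicate numbers were taken from the labels of the samples. Per the labels' protocols, poly(A) RNA was isolated with oligo(dT) beads, fragmented, reverse transcribed with random primers and sequenced on an Illumina HiSeq instrument. Poly(A) selection under-represents RNAs without a poly(A) tail, such as most replication-dependent histone mRNAs. The protocol names no step that keeps the strand, so reads of a gene and of an overlapping antisense gene cannot be told apart here.

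The authors deposited 1 table with a value per gene and sample, and the values were taken as FPKM, fragments divided by transcript length and by the total fragments of the library. The table's header gives no unit. FPKM was inferred from the values, which have 2 decimals and sum to a different total in each library, and from RSEM being named in the submitters' processing notes, since RSEM gives FPKM beside TPM and expected counts. Those notes also name HISAT, Bowtie2 and the genome build hg38. Versions, roles, settings and the gene annotation are not given in the sources used here, nor is any scaling between libraries beyond FPKM. RSEM divides reads that match several genes between them, so values of near-identical genes are less certain than others. FPKM is a share of each library, so a large rise of a few abundant genes lowers the values of all others. The table holds no read counts, and the smallest values are rounded to 0.01, so the depth of a library and the counting error of a value are unknown.

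The table listed 19479 genes by symbol, of which 477 were at 0 in every library. For 25 genes the symbol had been turned into a calendar date, as spreadsheet programs do. These were kept in the tests (19 of them passed the filter) and were not named. Coordinates are those of the symbols in GENCODE release 29 on hg38, counted from 1, which held 12420 of the 12729 genes tested. The annotation behind the deposited values may differ from it.

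Genes with at least 1 FPKM in at least 3 samples were tested, 12729 in all. Values were analysed as log2(FPKM + 1), so a fold change understates the change of genes with low values, and every log2 fold change and fold below is on this scale. Groups were compared with limma 3.58.1 in R 4.3.3 (linear model with 4 group means fitted to all 12 samples, empirical Bayes with a mean-variance trend and robust settings). The tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested within each comparison, and a gene was called at an adjusted p under 0.05. All adjusted p-values of genes come from this limma fit. The 5 comparisons were the drugs in empty-plasmid cells, DPF3 without drugs, the drugs in DPF3 cells, DPF3 with drugs, and the interaction, which is the drug effect in DPF3 cells minus that in empty-plasmid cells. Means are given with the SD over 3 libraries and log2 fold changes with their standard error (SE).

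The design, the tests, the alternatives, the 33 gene lists and the rule for naming genes were fixed before the data were examined, except where a choice is said to have been made later. The lists held 776 genes, of which 762 were matched. None of the 13 mitochondrially encoded genes could be matched, so that list was not analysed here, and the other 32 were tested. Lists were tested with limma's camera, which asks whether the members of a list differ from the other genes, with a preset correlation of 0.01 between members and Benjamini-Hochberg adjustment over the lists of a comparison. Adjusted p-values of lists are from camera. Camera was run again with the correlation estimated from the residuals of each list, because members of a list that vary together make the preset value too small. In empty-plasmid cells with the drugs, the neuronal and astrocyte lists kept their call with the estimated correlation, in DPF3 cells with the drugs the neuronal list did, and no list did in the other 3 comparisons. Members called were also counted with p-values adjusted over the list alone. Only members that passed the filter are counted, such as 13 of 22 neuronal, 16 of 26 astrocyte, 4 of 10 epithelial and 3 of 9 endothelial markers. A member that passed only through the group where it was high can differ in that direction alone, so lists with low values lean that way.

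In each comparison DPF3 was named, with the 8 genes of largest positive and the 8 of largest negative log2 fold change among called genes with a mean of at least 5 FPKM, whose 3 and 3 samples did not overlap (this last condition was not used for the interaction). From each list described, up to 4 members with the smallest adjusted p were named, and, among members that did not pass, those with the highest mean. Some genes that this rule names, and 1 of the lists, are not reported here. Genes outside this rule are said to have been chosen after their values were seen.

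Replicate numbers are shared by the groups in the labels. The deviations of same-numbered libraries from their group means were correlated across genes for every pair of groups compared. The correlations were 0.300 to 0.518 between the plasmids without drugs and 0.208 to 0.340 with drugs, so the numbers were taken to pair the samples in the DPF3 comparisons, and blocked values are given beside those results where they change a call or move a count by over 1.5 times. They were 0.0832 to 0.195 between drug and no drug in empty-plasmid cells and 0.0176 to 0.271 in DPF3 cells, where not every pair passed 0.1, so those comparisons were not treated as paired.

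The alternatives were quantile normalization of the log2 values, median-ratio scaling, no filter on low values, a mean of at least 5 FPKM, limma without trend and robust settings, array weights, a pseudocount of 0.1, only the 2 groups compared, the replicate number as a block, and each library left out in turn. Scaling of each library to the same sum of FPKM, and the block combined with the 2 groups alone or with the estimated correlation, were added after seeing the data. The statistics were tested on simulated data made from the means and spread of the 12729 genes, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold in each comparison. In the simulated comparison of the drugs in empty-plasmid cells, limma called 46.3% of the genes changed 1.5-fold, 83.6% of those changed 2-fold and 100% of those changed 4-fold. For DPF3 without drugs these shares were 44.8%, 73.1% and 93.9%, for the drugs in DPF3 cells 35.8%, 76.1% and 98.5%, for DPF3 with drugs 31.3%, 77.6% and 95.5%, and for the interaction 14.9%, 59.7% and 86.4%. Unchanged genes made up 3.16% to 6.84% of the simulated calls, and none of 20 lists without an effect was called in any comparison. In each simulation 12504 of the 12729 genes were unchanged, while 9446 and 9288 genes were called in the real drug comparisons. The adjustment was therefore stricter than in those, and the shares do not give what was found there. The 4 comparisons between groups were simulated with the same means, spread and number of samples, so differences between their shares come from the draw. The simulated genes varied independently of each other. The result therefore does not cover lists whose members vary together, such as G2 and M phase genes, with an estimated correlation of 0.80 for the drugs in empty-plasmid cells. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were handled with numpy 2.4.6 and pandas 2.3.3.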

Results

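Poly(A) RNA was sequenced from U87 cells that carried an empty plasmid or a plasmid for DPF3, a subunit of the BAF chromatin remodelling complex that binds modified histones. Cells of each kind were left without drugs or were given the cell-permeable cAMP analogue 8-cpt-cAMP (0.5 mM) together with MS275, an inhibitor of class I histone deacetylases (1 nM, as the labels give it, which is low for this inhibitor), for 48 h. The design asks what the drugs do, what DPF3 does, and whether DPF3 changes the response to the drugs. The drugs were given together, so their separate effects were not measured. Each of the 4 groups held 3 samples. Nothing says that these came from separate cultures, or that each plasmid was introduced more than once, so the p-values measure only the spread between these samples, which may be technical.

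The sums of FPKM per library were 413716 to 449427 in empty-plasmid cells without drugs, 390950 to 403513 with drugs, 415051 to 416781 in DPF3 cells without drugs and 399134 to 431266 with drugs. They are not read counts, and the depth is unknown. The number of genes listed at 0 was lower in every library with drugs (1716 to 1738 in empty-plasmid cells and 2034 to 2221 in DPF3 cells) than in any library without them (2945 to 2971 and 2874 to 3066). The 10 most abundant genes held 8.52% to 8.83% of the FPKM sum in empty-plasmid cells without drugs and 6.94% to 7.80% in DPF3 cells without drugs, against 11.6% to 12% and 11.5% to 11.8% with drugs. Principal component 1 of the 12729 tested genes held 79.3% of the variance and separated the libraries with drugs from those without. Component 2 held 9.41% and separated the plasmids.

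**Figure D1:**
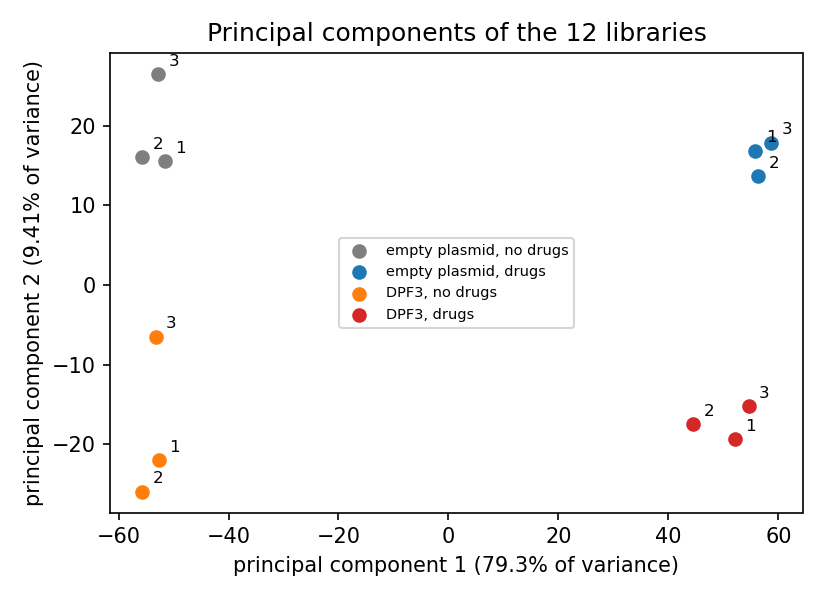
Principal components of log2(FPKM + 1) over the 12729 tested genes, 1 point per library with its replicate number, coloured by group. Component 1 (79.3% of the variance) parts the 6 libraries with drugs on the right from the 6 without on the left, and component 2 (9.41%) parts the empty-plasmid libraries above from the DPF3 libraries below.

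DPF3 RNA was 331-fold higher in cells with the DPF3 plasmid than in cells with the empty plasmid when no drugs were given. The gene lies on the minus strand of chromosome 14 at 72619296 to 72894116 (hg38), and gene-level values do not separate RNA of the plasmid from RNA of this locus. Its mean was 1.58 ± 0.384 FPKM (SD, n = 3) with the empty plasmid and 851 ± 105 FPKM (n = 3) with the DPF3 plasmid, a log2 fold change of 8.37 (SE 0.13, adjusted p = 3.76e-14). With the drugs the means were 1.82 ± 0.190 and 2458 ± 253 FPKM (n = 3 each), a log2 fold change of 9.76 (SE 0.13, adjusted p = 4.72e-15). Within DPF3 cells the drugs raised DPF3 2.89-fold (log2 fold change 1.53, SE 0.13, adjusted p = 2.11e-07). In empty-plasmid cells the drugs gave a log2 fold change of 0.14 (SE 0.13, adjusted p = 0.337), and the difference between these drug effects passed the test (interaction 1.39, SE 0.18, adjusted p = 0.000711). The plasmids were therefore compared at a higher DPF3 RNA level with drugs than without.

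**Figure D2:**
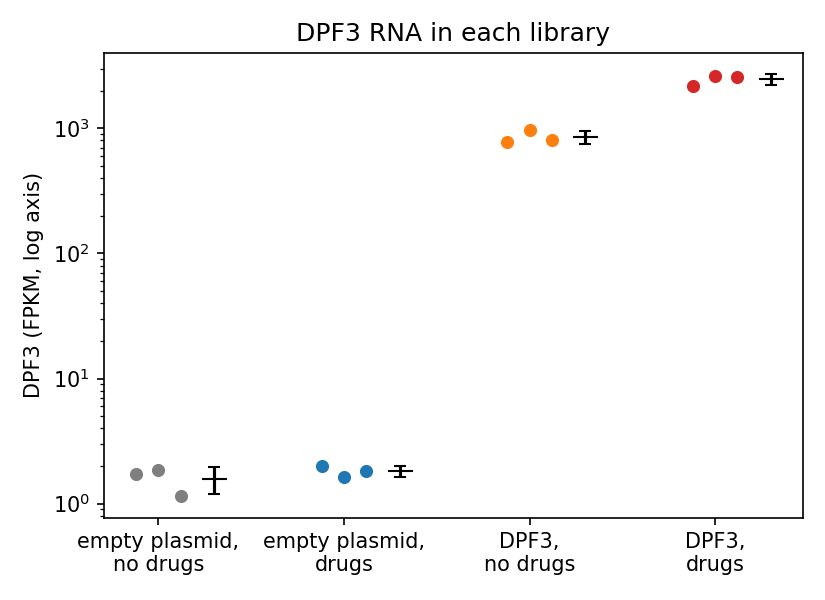
DPF3 in FPKM on a log axis, 1 point per library in each of the 4 groups, with the mean (horizontal line) and the SD (bars, n = 3) beside the points. The 6 libraries with the empty plasmid lie between 1.14 and 2.01 FPKM, and the DPF3 libraries lie between 777 and 971 FPKM without drugs and between 2169 and 2641 FPKM with drugs.

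The lists of neuronal and astrocyte markers were higher with the drugs in empty-plasmid cells. Hypoxia and glycolysis lists were called higher and cell-cycle and interferon lists lower, but these calls were lost with an estimated correlation. The genes with the largest rises were S100A9 and S100A8, calcium-binding proteins that form calprotectin and lie on chromosome 1 at 153357854 to 153361027 and 153390032 to 153391188. S100A9 went from 0.45 ± 0.09 to 217 ± 69.8 FPKM and S100A8 from 0.16 ± 0.139 to 107 ± 26.3 FPKM (SD, n = 3 each). RARRES2, the secreted attractant chemerin, rose 75.6-fold, the carboxylesterase CES1 65.0-fold and the cell adhesion gene CADM3 46.9-fold. The metallothionein MT1G rose 46.4-fold, the cytokine IL11 39.5-fold and EGLN3, an oxygen-sensing prolyl hydroxylase, 35.1-fold. The largest falls were those of RARRES3, a phospholipase gene (from 36 ± 8.47 to 0.317 ± 0.204 FPKM), and NUPR1, a stress-induced regulator of transcription (from 410 ± 62.8 to 15.8 ± 0.387 FPKM). Other large falls were those of the interferon-induced genes TRIM22 (35.7 ± 1.44 to 0.687 ± 0.217 FPKM), UBA7 (22.8 ± 0.857 to 0.25 ± 0.0656 FPKM) and IFI35 (34.0 ± 3.85 to 1.04 ± 0.463 FPKM). The stress-response transcription factor ATF5 fell from 73.9 ± 6.45 to 2.66 ± 0.690 FPKM, the quinone reductase NQO1 from 120 ± 5.32 to 5.79 ± 0.387 FPKM, and UBE2C, a ubiquitin-conjugating enzyme of mitosis, from 34.7 ± 24.7 to 0.667 ± 0.161 FPKM. The adjusted p-values of these 16 genes ranged from 1.99e-11 (UBA7) to 2.17e-06 (UBE2C).

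Of the 12729 genes, limma called 9446 for the drugs in empty-plasmid cells, 2982 higher and 6464 lower, and 3208 of them changed at least 2-fold (1221 higher, 1987 lower). The 3 and 3 libraries did not overlap for 76.1% of genes, where chance gives 10%. The share of calls that were higher was 31.6%, and it depended on the scaling, being 44.7% after quantile normalization and 51.7% after median-ratio scaling. The median log2 fold change of all genes was -0.31 on the values as deposited, -0.09 after quantile normalization and 0.01 after median-ratio scaling, so small falls are to be read against that median.

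All 20 tested hypoxia genes rose with the drugs in empty-plasmid cells, and so did 20 of 24 glycolysis genes, with 1 lower. NDRG1, a hypoxia-induced stress gene, rose 10.7-fold, and the collagen prolyl hydroxylase P4HA1 rose from 26.2 ± 2.46 to 178 ± 39.6 FPKM. The glucose transporter SLC2A1, which is in both lists, rose 10.4-fold, and SLC16A3, which exports lactate, rose 6.35-fold. The call was made by camera for hypoxia genes (adjusted p = 4.20e-12, and adjusted p = 0.125 with an estimated correlation) and for glycolysis (adjusted p = 1.04e-08, and adjusted p = 0.156 with an estimated correlation). Among neuronal markers 11 of 13 rose and none fell, and this call held with an estimated correlation (adjusted p = 0.0185). The synaptic vesicle genes SYP and SYN1 went from 1.17 ± 0.195 to 39.9 ± 1.96 FPKM and from 0.193 ± 0.0777 to 9.94 ± 0.956 FPKM. STMN2, a neuronal regulator of microtubules, went from 0.01 ± 0.0173 to 3.74 ± 0.206 FPKM. The dendritic microtubule gene MAP2 (adjusted p = 0.0881) and the growth cone gene GAP43 (adjusted p = 0.919) did not pass. Among astrocyte markers 13 of 16 rose and 2 fell, a call that also held with an estimated correlation (adjusted p = 0.0376). The lipid carrier APOE rose 15.5-fold, the sodium pump subunit ATP1B2 8.72-fold and ID4, an inhibitor of basic helix-loop-helix factors, 7.09-fold. The secreted chaperone CLU was at 376 ± 21.8 and 396 ± 53.9 FPKM (adjusted p = 0.591). Of the listed markers, 13 of 22 neuronal and 16 of 26 astrocyte genes passed the filter. A gene under 1 FPKM in all untreated libraries, such as STMN2 or SYN1, passed only because libraries with drugs reached 1 FPKM. The filter therefore favours rises in the counts and calls of both lists.

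Targets of cAMP signalling, of histone deacetylase inhibition and of TGF-beta were higher in empty-plasmid cells with the drugs. Of 25 cAMP-CREB target genes 17 rose and 3 fell (adjusted p = 1.88e-06, and adjusted p = 0.125 with an estimated correlation). They included the transcription factor FOS (5.02-fold), the cAMP phosphodiesterase PDE4D (9.35-fold) and the MAP kinase phosphatase DUSP1 (7.35-fold). Of 19 genes known to be induced by histone deacetylase inhibitors 12 rose and 4 fell (adjusted p = 0.000972, and adjusted p = 0.223 with an estimated correlation). The metallothionein MT1X rose 13.7-fold and the dehydrogenase DHRS2 13.8-fold. The neuronal phosphoprotein gene CRMP1 fell from 18.1 ± 1.94 to 6.21 ± 0.425 FPKM, and CDKN1A, an inhibitor of cyclin-dependent kinases, was at 90.4 ± 17.2 and 112 ± 4.48 FPKM (adjusted p = 0.0891). Of 21 TGF-beta target genes 16 rose and 3 fell (adjusted p = 1.87e-07, and adjusted p = 0.125 with an estimated correlation). Among them were PMEPA1, a feedback inhibitor of that pathway (14.2-fold), and ID2, an inhibitor of basic helix-loop-helix factors (16.1-fold). Camera also called NF-kB and cytokine genes (10 higher and 7 lower of 25, adjusted p = 0.588 with an estimated correlation), extracellular matrix genes (13 and 9 of 31, adjusted p = 0.432 with an estimated correlation), Wnt targets (6 and 4 of 11, adjusted p = 0.237 with an estimated correlation), receptor tyrosine kinase feedback genes (12 and 7 of 25, adjusted p = 0.221 with an estimated correlation) and epithelial cell markers (4 and 0 of 4, adjusted p = 0.223 with an estimated correlation). After quantile normalization these 5 calls were lost, with adjusted p = 0.10, 0.0705, 0.116, 0.0701 and 0.0705 in that order. In the epithelial list ELF3 passed the filter only through empty-plasmid libraries with drugs, which favours a rise.

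The drugs lowered 45 of 52 G2 and M phase genes in empty-plasmid cells and raised 1, and lowered 34 of 41 S phase genes and raised none. The mitotic cyclin CCNB2 fell from 13.7 ± 6.53 to 0.22 ± 0.0346 FPKM and the kinetochore gene CENPF from 8.77 ± 3.53 to 0.36 ± 0.0608 FPKM. The replicative helicase subunit MCM6 fell from 12.9 ± 1.18 to 1.59 ± 0.170 FPKM and UNG, which removes uracil from DNA, from 26.8 ± 1.79 to 9.16 ± 0.229 FPKM. Camera called both lists (adjusted p = 0.000264 and 0.00277), with adjusted p = 0.599 with an estimated correlation for each. Of 29 interferon-stimulated genes 24 fell and 5 rose (adjusted p = 0.394 with an estimated correlation). IFIT3, an antiviral gene, fell from 12.2 ± 0.633 to 1.5 ± 0.110 FPKM, and IRF9, the DNA-binding part of the interferon-activated ISGF3 complex, from 10.4 ± 0.954 to 2.27 ± 0.188 FPKM. Of 16 heat shock proteins 12 fell and 1 rose (adjusted p = 0.526 with an estimated correlation). The small chaperone HSPB1 fell from 415 ± 52.1 to 116 ± 7.74 FPKM and the mitochondrial chaperonin HSPD1 from 179 ± 27.7 to 53.8 ± 4.88 FPKM. The constitutive chaperone HSPA8 was at 564 ± 135 and 535 ± 70.4 FPKM (adjusted p = 0.775). The counts adjusted over the list alone were equal to those over all genes for each of the 16 lists called in empty-plasmid cells with the drugs.

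The remaining 16 lists were not called as groups in empty-plasmid cells with the drugs, although many of their members were. Of 26 BAF complex subunits 18 fell and 3 rose, among them the core subunit SMARCB1 (43.3 ± 3.61 to 12 ± 1.21 FPKM) and the bromodomain subunit BRD9 (15.9 ± 0.825 to 4.48 ± 0.197 FPKM). The subunit SMARCD3 rose from 21.5 ± 0.798 to 49.9 ± 3.32 FPKM. Of 18 cyclins, CDKs and related regulators 8 fell and 6 rose. The G1 cyclin CCND1 fell from 103 ± 6.33 to 12.9 ± 0.561 FPKM, and the CDK inhibitor CDKN1C rose from 0.217 ± 0.0569 to 5.05 ± 1.89 FPKM. The numbers higher and lower were 5 and 16 of 24 for apoptosis regulators, and 4 and 14 of 24 both for histone deacetylases and acetyltransferases and for the unfolded protein and integrated stress response. They were 3 and 13 of 24 for cholesterol biosynthesis, 5 and 13 of 23 for components of the cAMP pathway, 4 and 20 of 45 for nuclear-encoded oxidative phosphorylation, and 2 and 27 of 42 for ribosomal proteins. For neural stem markers they were 7 and 6 of 14, for cytoskeletal and muscle genes 6 and 7 of 15, and for oligodendrocyte lineage markers 2 and 1 of 4. Markers of cell types not named in the labels gave 3 and 2 of 5 for immune cells, 1 and 0 of 3 for endothelial cells, and 2 and 3 of 7 for pericytes and smooth muscle. Adjusted over the list alone these counts were equal except for cAMP pathway components (6 and 13) and oxidative phosphorylation (4 and 18). After quantile normalization the numbers higher and lower were 11 and 14 for oxidative phosphorylation, 10 and 12 for histone deacetylases and acetyltransferases, 8 and 9 for cAMP pathway components and 5 and 7 for cholesterol biosynthesis, so the excess of falls in these lists depended on the scaling. Ribosomal proteins were called lower after quantile normalization (adjusted p = 0.000208), and after median-ratio scaling their numbers were 8 higher and 7 lower. Between scalings the medians of oxidative phosphorylation, ribosomal proteins, endothelial markers, cyclins, cytoskeletal genes and pericyte markers changed sign, and for the last 3 camera's direction was upward while the median was below 0.

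Without drugs, the stress response list was lower and the glycolysis and cell-cycle lists were higher in DPF3 cells, and no list kept its call with an estimated correlation. IL36RN and IL36B, an antagonist and an agonist of the interleukin-36 receptor that are neighbours on chromosome 2 (113058638 to 113065382 and 113022091 to 113052867), were lower in DPF3 cells, at 1.46 ± 0.847 against 38.7 ± 10.2 FPKM and at 2.35 ± 1.00 against 54.2 ± 19.6 FPKM (SD, n = 3 each). The epidermal secreted gene DMKN was at 3.78 ± 0.498 against 43.2 ± 6.95 FPKM (adjusted p = 3.61e-09) and the integrin subunit ITGAX at 0.42 ± 0.165 against 7.89 ± 2.48 FPKM. CHI3L1, a secreted glycoprotein abundant in glioblastoma, was at 278 ± 66.4 against 1878 ± 381 FPKM, and GPNMB, a transmembrane glycoprotein, at 41.6 ± 14.5 against 246 ± 85.2 FPKM. The cytokines IL1B (9.0 ± 4.61 against 98.1 ± 48.0 FPKM, adjusted p = 0.00949) and CSF3 (63.6 ± 33.2 against 355 ± 92.1 FPKM, adjusted p = 0.0117) were lower too. After DPF3 itself, the largest rises were those of the imprinted gene MEST (43.2 ± 21.9 against 7.23 ± 2.16 FPKM), the matrix proteoglycan VCAN (42.6 ± 10.2 against 9.68 ± 2.90 FPKM), ID3, an inhibitor of basic helix-loop-helix factors (38.3 ± 9.62 against 9.80 ± 3.36 FPKM), and NREP, a regeneration-related gene of neurons (25.2 ± 7.80 against 6.17 ± 2.30 FPKM). CPA4, a carboxypeptidase, was 3.66-fold higher, SFRP2, a secreted Wnt modulator, 3.58-fold, and SYNPO, an actin-associated gene, 3.53-fold.

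Limma called 1890 genes for DPF3 without drugs, 1007 higher and 883 lower, and 311 of these differed at least 2-fold (147 higher, 164 lower). The 3 and 3 libraries did not overlap for 32.3% of genes, where chance gives 10%. The count was 1031 without replicate 3 of the empty-plasmid cells, and 972 and 978 without replicates 1 and 2 of the DPF3 cells. It was 1232 with only these 2 groups in the fit, 2969 with these groups and the replicate block, and 3290 with array weights.

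Genes of the unfolded protein and integrated stress response were lower in DPF3 cells without drugs, with 15 of 24 called lower and none higher (1 higher and 19 lower adjusted over the list alone). The chaperones DNAJB9 and HSPA5 of the endoplasmic reticulum were at 11 ± 4.01 against 29.8 ± 4.35 FPKM and at 301 ± 60.9 against 543 ± 101 FPKM. TRIB3, a pseudokinase induced by ATF4, was at 21.4 ± 16.5 against 71.8 ± 20.8 FPKM, and CALR, a calcium-binding chaperone, at 730 ± 110 against 620 ± 57.3 FPKM (adjusted p = 0.262). Camera called this list (adjusted p = 9.45e-08), with adjusted p = 0.554 with an estimated correlation. Among NF-kB and cytokine genes 6 of 25 were lower and 1 higher (7 and 1 adjusted over the list alone, 7 and 2 with the replicate block), and they included IL6 (51.1 ± 34.3 against 207 ± 80 FPKM) and the adhesion molecule ICAM1 (14.6 ± 4.52 against 30.5 ± 2.56 FPKM). Glycolysis genes were higher for 10 of 24 (12 higher and 1 lower adjusted over the list alone), such as lactate dehydrogenase LDHA (781 ± 264 against 284 ± 99.3 FPKM) and SLC16A3 (64.0 ± 5.15 against 43.0 ± 3.36 FPKM). The glycolytic GAPDH was at 3785 ± 546 against 2994 ± 697 FPKM (adjusted p = 0.289). Of 21 TGF-beta targets 7 were higher and 3 lower (9 and 3 adjusted over the list alone), with ID3 and the inhibitory SMAD6 (1.93-fold) among the higher ones. Cholesterol biosynthesis had 4 of 24 higher (6 adjusted over the list alone, 9 with the replicate block and only the 2 groups), such as the thiolase ACAT2 (2.16-fold) and the farnesyl diphosphate synthase FDPS (1.58-fold). Cytoskeletal and muscle genes had 2 of 15 higher (2 adjusted over the list alone), the calponin CNN2 (2.10-fold) and the myosin heavy chain MYH9 (1.5-fold). With an estimated correlation the adjusted p was 0.554 for each of these 6 lists.

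Cell-cycle lists were shifted upward in DPF3 cells without drugs, though few single members passed without the replicate block. Of 52 G2 and M phase genes all 52 had a log2 fold change above 0, 7 were called over all genes and 24 adjusted over the list alone, and the replicate block gave 24 over all genes, and 47 with only the 2 groups in the fit (adjusted p = 4.26e-10 by camera, and adjusted p = 0.554 with an estimated correlation). ECT2, which directs cytokinesis, was at 17.2 ± 5.13 against 9.78 ± 1.43 FPKM, and the checkpoint kinase BUB1 at 12.5 ± 5.99 against 4.92 ± 2.55 FPKM. Of 41 S phase genes 40 were above 0, 8 were called (16 adjusted over the list alone, 15 with the replicate block, 19 with it and only the 2 groups), and the adjusted p was 0.554 with an estimated correlation. They included the replication checkpoint gene CLSPN (1.66-fold). Of 45 nuclear-encoded oxidative phosphorylation genes 42 lay above 0 with a median log2 fold change of 0.17. None was called over all genes or adjusted over the list alone, 6 were with the replicate block and 3 with it and only the 2 groups, and the adjusted p was 0.645 with an estimated correlation. Extracellular matrix genes, with 9 higher and 4 lower of 31 (11 and 5 adjusted over the list alone), were called as a list with the block (adjusted p = 0.0369, and adjusted p = 0.562 with an estimated correlation) and not without it (adjusted p = 0.0887). Among the 26 BAF subunits 2 were called (1 adjusted over the list alone), DPF3 itself and its paralog DPF1 (2.90 ± 1.83 against 0.953 ± 0.306 FPKM, adjusted p = 0.0378).

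Several of these single calls were lost with 1 library left out, where fewer samples enter. Without replicate 3 of the untreated empty-plasmid cells, the adjusted p was 0.0541 for IL1B and for IL6, 0.0676 for CSF3, 0.0557 for FDPS, 0.0659 for ECT2, 0.0965 for BUB1 and 0.0613 for CLSPN. Their log2 fold changes were then -3.14 for IL1B (-3.29 with all libraries), -2.31 for IL6 (-2.25), -2.54 for CSF3 (-2.59), 0.55 for FDPS (0.66), 0.64 for ECT2 (0.72), 0.87 for BUB1 (1.18) and 0.68 for CLSPN (0.73). Without replicate 2 of the untreated DPF3 cells it was 0.0576 for CSF3, 0.0677 for ECT2 and 0.0922 for BUB1. It was 0.0598 for FDPS and 0.0732 for BUB1 without replicate 1 of the DPF3 cells, and 0.0588 for BUB1 without replicate 1 of the empty-plasmid cells. DPF1 lost its call without replicate 1 or 3 of the untreated empty-plasmid cells, replicate 2 of the treated ones, or replicate 1 or 2 of the untreated DPF3 cells (adjusted p from 0.0501 to 0.125), after quantile normalization (0.0700) and without the filter (0.0610). Without replicate 2 of the untreated DPF3 cells the log2 fold change was 0.55 for DPF1, against 0.91 with all libraries, and 0.48 for CLSPN, against 0.73. With only the 2 groups in the fit the adjusted p was 0.0530 for CPA4, 0.0501 for TRIB3, 0.0688 for IL6, 0.0574 for ECT2, 0.118 for BUB1, 0.0684 for CLSPN and 0.102 for DPF1. With the replicate block in that fit it was 0.0754 for IL1B, 0.0625 for CSF3, 0.123 for TRIB3 and 0.215 for IL6.

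In DPF3 cells 15 of the 16 lists called in empty-plasmid cells were called for the drugs, but only neuronal markers kept the call with an estimated correlation. Mitotic genes showed the largest falls. The other list, receptor tyrosine kinase feedback genes, had 9 of 25 higher and 9 lower (adjusted p = 0.150). UBE2C fell from 68.3 ± 42.4 to 0.55 ± 0.139 FPKM (SD, n = 3 each), CDC20, which activates the anaphase-promoting complex, from 39.1 ± 20.7 to 0.18 ± 0.0794 FPKM, and the mitotic transcription factor FOXM1 from 36 ± 12.1 to 0.42 ± 0.0854 FPKM. The survivin gene BIRC5 fell from 32.1 ± 17.7 to 0.21 ± 0.10 FPKM, the kinase PLK1 from 34.3 ± 19.1 to 0.473 ± 0.0702 FPKM, and the cyclins CCNB1 from 40.5 ± 19.4 to 0.87 ± 0.0656 FPKM and CCNB2 from 24.2 ± 11.6 to 0.16 ± 0.0520 FPKM. The kinetochore gene ZWINT fell from 30.2 ± 16.2 to 0.583 ± 0.201 FPKM. The largest rises were those of S100A9 (42.1-fold), CES1 (37.7-fold), S100A8 (32.3-fold), EGLN3 (28.8-fold), DDIT4L, a negative regulator of mTOR signalling (26.4-fold), HAS1, a hyaluronan synthase (26.4-fold), the elastase inhibitor PI3 (25.7-fold) and TMEM59L, a membrane protein gene of the brain (23.1-fold). HAS1 went from 48.4 ± 8.05 to 1324 ± 348 FPKM. The adjusted p-values of these 16 genes ranged from 1.27e-10 (TMEM59L) to 1.86e-06 (S100A8).

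Limma called 9288 genes for the drugs in DPF3 cells, 2759 higher and 6529 lower, and 2968 of them changed at least 2-fold (950 higher, 2018 lower). The share higher was 29.7%, against 46.6% after quantile normalization and 51.4% after median-ratio scaling, with a median log2 fold change of all genes of -0.32 on the values as deposited. The libraries of the 2 groups did not overlap for 75.5% of genes.

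All 20 hypoxia genes rose in DPF3 cells with the drugs, such as NDRG1 (101 ± 18.5 to 1632 ± 250 FPKM), and 19 of 24 glycolysis genes rose with 1 lower (adjusted p = 0.125 and 0.136 with an estimated correlation). Neuronal markers had 12 of 13 higher and 1 lower, a call that held with an estimated correlation (adjusted p = 0.00845). SYP went from 1.16 ± 0.420 to 47.6 ± 6.49 FPKM, STMN2 from 0.0433 ± 0.0404 to 5.84 ± 1.25 FPKM and the secretogranin SCG2 from 2.74 ± 0.917 to 25.3 ± 2.52 FPKM. Astrocyte markers had 11 of 16 higher and none lower, with APOE 12.1-fold and ID4 7.46-fold higher and the protease inhibitor CST3 at 152 ± 1.23 and 140 ± 19.2 FPKM (adjusted p = 0.308). The astrocyte call was lost with adjusted p = 0.0542 with an estimated correlation. As in empty-plasmid cells, the filter favours rises in the neuronal and astrocyte lists. The cAMP-CREB targets had 18 of 25 higher and 1 lower (adjusted p = 0.125 with an estimated correlation), with PDE4D 12.5-fold and DUSP1 8.65-fold higher. NF-kB and cytokine genes had 12 higher and 7 lower of 25 (adjusted p = 0.455 with an estimated correlation), and CXCL8 went from 73.3 ± 46.9 to 1204 ± 262 FPKM, CCL20 from 0.947 ± 0.660 to 35.4 ± 10.1 FPKM and IL11 from 1.59 ± 0.242 to 13.6 ± 6.02 FPKM. Genes induced by histone deacetylase inhibitors (12 higher and 4 lower of 19, adjusted p = 0.211 with an estimated correlation) and TGF-beta targets (14 and 3 of 21, adjusted p = 0.125 with an estimated correlation) were called higher as well.

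G2 and M phase genes fell for 49 of 52 members in DPF3 cells with the drugs and S phase genes for 39 of 41 (40 adjusted over the list alone), with none higher in either list. Their adjusted p was 0.472 and 0.455 with an estimated correlation. CENPF fell from 16.9 ± 7.03 to 0.347 ± 0.0379 FPKM and MCM6 from 16.2 ± 5.53 to 1.35 ± 0.154 FPKM. Interferon-stimulated genes fell for 23 of 29 and rose for 4 (adjusted p = 0.362 with an estimated correlation), with IFIT3 going from 9.75 ± 1.01 to 2.42 ± 0.146 FPKM and the guanylate-binding GBP1 from 6.71 ± 1.19 to 0.573 ± 0.0513 FPKM. Heat shock proteins fell for 13 of 16 and rose for 1 (adjusted p = 0.455 with an estimated correlation). Extracellular matrix genes (12 higher and 11 lower of 31), Wnt targets (7 and 3 of 11) and epithelial markers (2 and 0 of 4) were called higher by camera, with adjusted p = 0.455, 0.175 and 0.355 with an estimated correlation and 0.303, 0.0563 and 0.215 after quantile normalization. Apart from S phase genes, the counts adjusted over the list alone were equal to those over all genes for the 15 lists called.

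The drug responses of both kinds of cell had the same direction for most genes. Of the 9446 genes called in empty-plasmid cells, 96.2% (9090) had the same sign in DPF3 cells, and across all 12729 genes the log2 fold changes correlated with Pearson 0.912 and Spearman 0.901. These comparisons share no library, and genes are not independent replicates, so no p-value is given. Genes called higher in both numbered 2307, where independent lists would share 646, and genes called lower in both numbered 5674, where independent lists would share 3316. The median change of each list is plotted for the drug and the DPF3 comparisons.

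**Figure D3:**
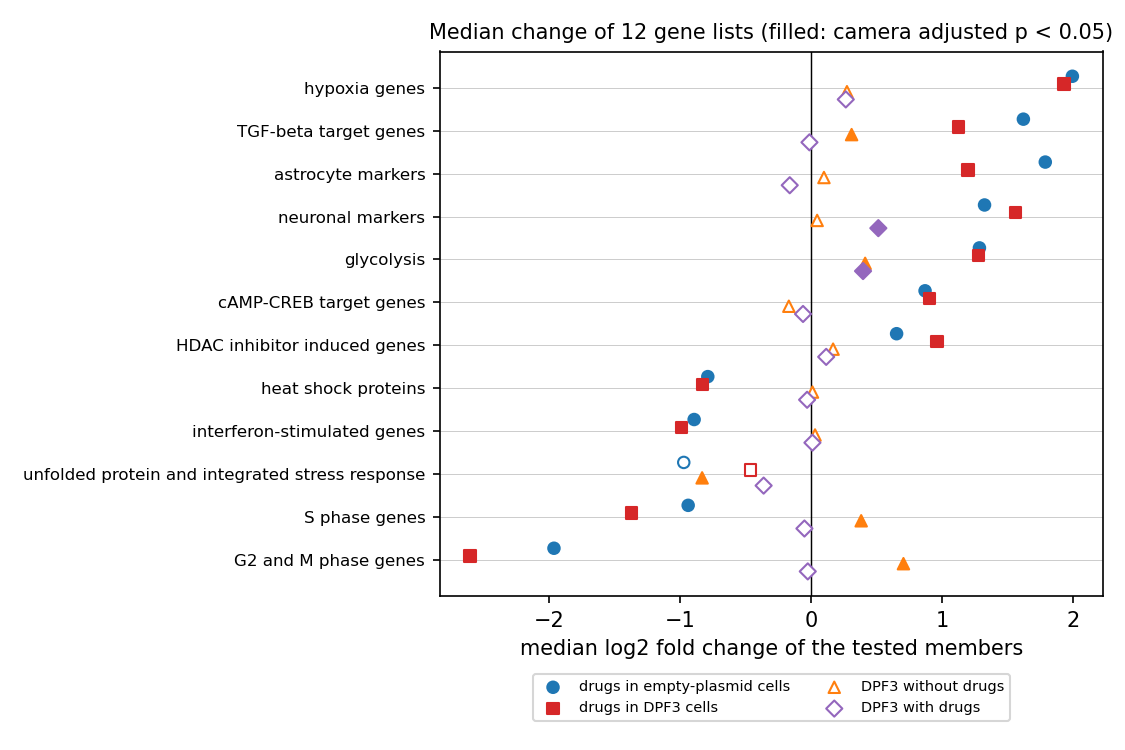
Median log2 fold change of the tested members of 12 gene lists (rows) in the 4 comparisons between groups, with filled symbols where camera gave an adjusted p under 0.05 with the preset correlation. Circles and squares for the drugs lie far from 0 on the same side in both kinds of cell, from 1.99 and 1.93 for hypoxia genes to -1.96 and -2.60 for G2 and M phase genes, and triangles and diamonds for DPF3 lie between -0.83 and 0.70.

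With the drugs present, DPF3 cells had less RNA of IL11 and RARRES2 than empty-plasmid cells and more of PLAU and RSPO3. IL11, on chromosome 19 at 55364389 to 55370463, was at 13.6 ± 6.02 FPKM in DPF3 cells against 186 ± 16.5 FPKM with the empty plasmid (SD, n = 3 each, log2 fold change -3.75, SE 0.22, adjusted p = 6.02e-07). RARRES2 was at 15.4 ± 7.48 against 126 ± 23.3 FPKM, CHI3L1 at 143 ± 49.1 against 906 ± 360 FPKM, ITGAX at 2.02 ± 0.322 against 16.4 ± 2.73 FPKM and APOE at 26.1 ± 6.07 against 149 ± 19.3 FPKM. The amino acid transporter SLC7A8 was at 6.48 ± 0.924 against 34.5 ± 9.83 FPKM and IL6 at 81.5 ± 19.3 against 374 ± 129 FPKM. PLAU, the urokinase plasminogen activator, was at 198 ± 34.3 against 40.1 ± 6.30 FPKM, and RSPO3, which strengthens Wnt signalling, at 51.6 ± 0.811 against 11.4 ± 0.889 FPKM. CPA4 was 4.28-fold higher, the neuropeptide precursor NTS 3.49-fold, SFRP2 3.33-fold, the pyruvate dehydrogenase kinase PDK4 3.26-fold and LYPD1, a membrane-anchored modulator of acetylcholine receptors, 3.18-fold. With only the 2 groups in the fit NTS lost its call (adjusted p = 0.0549, and 0.104 with the replicate block).

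Limma called 2249 genes for DPF3 with drugs, 940 higher and 1309 lower, and 284 of them differed at least 2-fold (77 higher, 207 lower). Which direction held more of the calls was not stable. Quantile normalization gave 1300 higher and 1217 lower, and genes with a mean of at least 5 FPKM gave 737 higher and 668 lower. The 3 and 3 libraries did not overlap for 36.6% of genes. The count was 1196 without replicate 3 of the empty-plasmid cells with drugs, 1405 among genes with a mean of at least 5 FPKM and 3496 with array weights.

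Neuronal markers were called as a list for DPF3 with drugs, with 6 of 13 higher and 2 lower (7 and 2 adjusted over the list alone, adjusted p = 0.370 with an estimated correlation). The vesicle calcium sensor SYT1 was at 14.2 ± 0.216 against 5.53 ± 0.666 FPKM, the neuronal tubulin TUBB3 at 165 ± 13.1 against 67.6 ± 17.5 FPKM and SCG2 at 25.3 ± 2.52 against 12.7 ± 0.943 FPKM. The synapsin SYN1 was lower, at 5.41 ± 1.12 against 9.94 ± 0.956 FPKM. Glycolysis had 7 of 24 higher (7 higher and 1 lower adjusted over the list alone, 13 and 1 with the replicate block and only the 2 groups, adjusted p = 0.696 with an estimated correlation), such as SLC16A3 (1.56-fold) and the aldolase ALDOA (1.58-fold). Oxidative phosphorylation had 2 of 45 higher (1 adjusted over the list alone, 6 with the replicate block, 9 with it and only the 2 groups, adjusted p = 0.963 with an estimated correlation), the complex I subunit NDUFB3 (1.48-fold) and the cytochrome oxidase subunit COX7C (1.32-fold). Receptor tyrosine kinase feedback genes had 9 of 25 lower and 1 higher (10 and 2 adjusted over the list alone, adjusted p = 0.370 with an estimated correlation). Among them were the pathway inhibitor SPRY4 (2.42 ± 0.158 against 5.14 ± 0.653 FPKM) and the transcription factors ETV5 (7.01 ± 0.192 against 12 ± 1.92 FPKM) and FOSL1 (6.44 ± 0.520 against 14.7 ± 2.43 FPKM). Endothelial markers had 2 of 3 lower and epithelial markers 2 of 4 (the same adjusted over the list alone, adjusted p = 0.577 with an estimated correlation for both). They were the receptor tyrosine kinase TIE1 (1.29 ± 0.402 against 7.74 ± 1.36 FPKM) and the adhesion molecule PECAM1 (0.507 ± 0.155 against 1.31 ± 0.408 FPKM), and the transcription factor ELF3 (0.513 ± 0.327 against 3.42 ± 0.935 FPKM) and the keratin KRT8 (5.72 ± 0.248 against 8.72 ± 0.388 FPKM). ELF3 passed the filter only through empty-plasmid libraries with drugs, and TIE1 was under 1 FPKM in all untreated libraries. The filter therefore favours falls with DPF3 in these short lists. The stress response list was not called (1 higher and 8 lower of 24, 1 and 9 adjusted over the list alone), with the asparagine synthetase ASNS (22.8 ± 6.48 against 81.7 ± 21.5 FPKM) and CHAC1, which degrades glutathione (4.33 ± 2.40 against 17.9 ± 6.86 FPKM), lower and CALR higher (922 ± 69.7 against 589 ± 59.2 FPKM). After quantile normalization the neuronal, glycolysis and endothelial calls were lost with adjusted p = 0.0600 each, oxidative phosphorylation with 0.0811, epithelial markers with 0.0738 and ALDOA with 0.0821. COX7C lost its call without replicate 1 or 3 of the untreated empty-plasmid cells, replicate 1, 2 or 3 of the treated ones, replicate 3 of the untreated DPF3 cells, or replicate 1 or 3 of the treated ones (adjusted p from 0.0502 to 0.163).

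DPF3 effects without and with drugs had the same sign for 77.4% of the 1890 genes called without drugs, and across all genes they correlated with Pearson 0.435 and Spearman 0.339. Genes called higher with DPF3 in both numbered 273, where independent lists would share 74.4, and genes called lower in both numbered 289, where independent lists would share 90.8. SFRP2 and CPA4 were among the largest rises and CHI3L1 and ITGAX among the largest falls in both comparisons.

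The interaction asks whether the drugs acted differently in DPF3 cells, and among the genes named here its largest values were those of IL36RN and IL11. IL11 rose from 3.74 ± 0.690 to 186 ± 16.5 FPKM with drugs in empty-plasmid cells and from 1.59 ± 0.242 to 13.6 ± 6.02 FPKM in DPF3 cells (interaction -2.88, SE 0.32, adjusted p = 0.000211). On the log2(FPKM + 1) scale RARRES2 (interaction -2.42), CADM3 (-1.94) and the glutamine transporter SLC38A3 (-1.92) also rose by less in DPF3 cells. So did PPP1R1A, an inhibitor of protein phosphatase that was listed at 0 in every untreated DPF3 library (-1.99). Without drugs the means of these genes were under 1 FPKM, where the added 1 FPKM sets much of the fold. RARRES2 went from 0.737 to 126 FPKM with the empty plasmid and from 0.0667 to 15.4 FPKM with DPF3. These interactions may largely restate a lower level in DPF3 cells with drugs. VCAN (-1.94), MEST (-2.19) and OLFML2B, an olfactomedin-like secreted gene (-2.29), were higher in untreated DPF3 cells than with the empty plasmid. In DPF3 cells MEST fell with drugs from 43.2 ± 21.9 to 10.8 ± 2.80 FPKM and OLFML2B from 34.3 ± 9.10 to 4.80 ± 0.597 FPKM, while VCAN was at 42.6 ± 10.2 and 30.7 ± 6.01 FPKM, a difference that did not pass (adjusted p = 0.106). Positive interactions were called for IL36RN (3.01), IL36B (2.04), the cornified envelope gene SPRR2D (2.39) and NQO1 (1.73), whose falls with drugs in empty-plasmid cells were larger than their changes in DPF3 cells. In DPF3 cells IL36RN was at 1.46 ± 0.847 FPKM without and 0.90 ± 0.219 FPKM with drugs. IL36B was at 2.35 ± 1.00 and 1.92 ± 0.675 FPKM. Both had little room to fall there, so their interactions may largely restate their lower level in untreated DPF3 cells. For RSPO3 (2.33) and KCTD4, a gene with a potassium channel tetramerization domain (1.82), the means were 18.6 ± 4.78 and 6.86 ± 0.638 FPKM without drugs and 11.4 ± 0.889 and 3.91 ± 0.459 FPKM with drugs in empty-plasmid cells, against 16.4 ± 7.63 and 5.41 ± 1.33 FPKM without and 51.6 ± 0.811 and 13.2 ± 3.71 FPKM with drugs in DPF3 cells. DMKN (1.91) went from 43.2 ± 6.95 to 92.5 ± 10.7 FPKM in empty-plasmid cells and from 3.78 ± 0.498 to 36.9 ± 0.996 FPKM in DPF3 cells. SPRR2D lost its call (adjusted p = 0.0450) with any 1 library left out except replicate 1 of the untreated empty-plasmid cells and replicate 3 of the untreated DPF3 cells, with adjusted p from 0.0527 to 0.119. It also lost it without the filter (0.0566), at a mean of at least 5 FPKM (0.0591), with array weights (0.0723) and with a pseudocount of 0.1 (0.0761). RARRES2 lost its call with a pseudocount of 0.1 (interaction -0.89, adjusted p = 0.545).

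Limma called 802 genes for the interaction, 289 positive and 513 negative, and 265 of them were at least 2-fold (94 positive, 171 negative). The drug effect had the same sign in both kinds of cell and was smaller in DPF3 cells for 442 of them (319 smaller rises and 123 smaller falls), had the same sign and was larger for 156, and had opposite signs for 204, of which 57 were called in both. The share positive was 36%, against 46.1% after quantile normalization and 25% after scaling to a common sum. Among genes with a mean of at least 5 FPKM 205 were positive and 196 negative, so the excess of negative values was not stable. The count was 525 without replicate 3 of the untreated empty-plasmid cells, 364 without replicate 3 of the treated ones, and 497, 498 and 1365 without replicates 1, 2 and 3 of the untreated DPF3 cells. It was 1235 with the replicate block, 401 among genes with a mean of at least 5 FPKM and 1872 with array weights.

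As lists, S phase, G2 and M phase and TGF-beta target genes had negative interactions and the stress response a positive one, and all 4 calls were lost with an estimated correlation. S phase genes had 3 of 41 called (10 adjusted over the list alone, 6 with the replicate block), such as the deubiquitinase USP1 (interaction -0.85), and G2 and M phase genes had 2 of 52 (2 adjusted over the list alone, 5 with the block), the heterochromatin protein CBX5 (-1.03) and the lamina gene TMPO (-1.31). TMPO lost its call without replicate 3 of the untreated empty-plasmid cells, replicate 1 or 3 of the treated ones, replicate 1 of the untreated DPF3 cells, or replicate 1 or 2 of the treated ones (adjusted p from 0.0541 to 0.0652). Of the TGF-beta targets 1 of 21 was called, the feedback gene SKIL (-0.93), with 4 adjusted over the list alone and 4 with the block. The stress response had 3 of 24 called (4 adjusted over the list alone), among them DNAJB9 (1.69) and HSPA5 (1.04), which fell with drugs in empty-plasmid cells and had means of 11 ± 4.01 and 301 ± 60.9 FPKM without and 16.4 ± 2.27 and 358 ± 12.3 FPKM with drugs in DPF3 cells. With an estimated correlation the adjusted p was 0.837 for S phase, G2 and M phase and stress response genes and 0.561 for TGF-beta targets, and after quantile normalization the stress response list had adjusted p = 0.113. Astrocyte markers were called with the block (adjusted p = 0.0326) and not without it (adjusted p = 0.0569), with an adjusted p of 0.561 with an estimated correlation and 1 positive and 4 negative of 16 (1 and 5 adjusted over the list alone), such as the glutamine synthetase GLUL (-0.77) and the gap junction gene GJA1 (-1.31).

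Across the 12729 genes the DPF3 effect averaged over drug status and the drug effect averaged over plasmid correlated with Pearson -0.0980 and Spearman -0.0954. The covariance was -0.0289. In this balanced design neither effect shares a control with the other. Simulated data with no effect and independent genes gave correlations of -0.0291 to 0.0323, and rotated residuals, which keep the correlation between genes, gave -0.396 to 0.418 and covariances of -0.00502 to 0.00556. The observed correlation lay within the range of the rotated residuals and the covariance below it. Both sets have no effect at all, so they do not decide whether DPF3 moved genes against the direction of the drugs. The correlation was -0.0112 among genes with a mean of at least 5 FPKM and -0.155 with a pseudocount of 0.1. The averaged DPF3 effect was called for 3277 genes and the averaged drug effect for 10343.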

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

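The counts over other splits of the samples were planned, and every other test of an explanation here was chosen after the result was seen, with 2 of them replacing tests that could not decide. The drug response differed between empty-plasmid and DPF3 cells for 802 genes by limma's interaction term. Regrouping the plasmid labels within each drug status gave a count as large in 1 of 100 regroupings drawn from 200, the real one. The highest other count was 260. The regrouped residuals keep any real interaction, which widens the spread within the regrouped groups and lowers their counts. The samples may also be technical, so a chance difference between cultures or populations is not excluded. In a check added later, the 31 other regroupings that part all same-numbered pairs in both drug statuses gave 0, and 260 came from one that does not. For the other comparisons 10 splits of 6 libraries are too few for a share under 0.05. The real counts were 9446 for the drugs in empty-plasmid cells, 1890 for DPF3 without drugs, 9288 for the drugs in DPF3 cells and 2249 for DPF3 with drugs, each reached by 1 of the 10 splits, and the highest count of any other split was 0. Among these, the 3 other splits that part all 3 same-numbered pairs in each DPF3 comparison also gave 0. Every other split mixes libraries of both groups, which widens the spread wherever the groups differ, so these counts of 0 decide nothing.

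Of the 131 genes named in the report by the rule, 38 had a called interaction, 23 negative and 15 positive. Many were named for their interaction, so this share comes from the naming, against 802 called of all 12729 genes. Negative values, where the log2 fold change with drugs was lower in DPF3 than in empty-plasmid cells, its direction being opposite for some genes, were those of IL11 (-2.88), RARRES2 (-2.42), OLFML2B (-2.29), MEST (-2.19), PPP1R1A (-1.99), VCAN (-1.94), CADM3 (-1.94) and SLC38A3 (-1.92). The transcription factors FOS (-1.70) and ELF3 (-1.48), the receptor TIE1 (-1.82), the actin-associated SYNPO (-1.60), NREP (-1.58), the CDK inhibitor CDKN1C (-1.36) and the gap junction gene GJA1 (-1.31) followed. Genes of the nucleus and cell division were TMPO (-1.31), CBX5 (-1.03) and USP1 (-0.85), and the others were ACAT2 (-1.14), SKIL (-0.93), GLUL (-0.77), CNN2 (-0.75) and SYN1 (-0.73). Positive values were those of IFIT3 (0.75), the synaptic SYT1 (0.88), the secretogranin SCG2 (0.96), the chaperones HSPA5 (1.04) and DNAJB9 (1.69), PLAU (1.26), PDK4 (1.32) and DPF3 itself (1.39). The largest were NQO1 (1.73), KCTD4 (1.82), DMKN (1.91), IL36B (2.04), RSPO3 (2.33), SPRR2D (2.39) and IL36RN (3.01). IL36B and IL36RN were low in untreated DPF3 cells, with little room to fall there. RARRES2, CADM3, PPP1R1A and SLC38A3 had means under 1 FPKM without drugs, where the added 1 FPKM sets much of the fold. RARRES2 lost its call with a pseudocount of 0.1 (interaction -0.89).

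Fewer genes were listed at 0 with drugs in both kinds of cell. Whether deeper libraries gave this cannot be told from the values. In empty-plasmid cells 34.3% of 99 untied genes seen in 1 library of each group were lower with drugs (95% interval 25.1% to 44.6%). In DPF3 cells the share was 35.5% of 110. Deeper libraries would give mostly lower values, but these genes lie near the floor. In empty-plasmid cells 47.9% of the 190 genes were tied, and values that round to 0 leave the set. The share of lower values replaced a median ratio that rounding to 0.01 had fixed at 1. A background of reads that depends on transcript length alone was argued against. The 148 genes newly above 0 that were shared by both kinds of cell were 3.21 times the 46.1 expected from transcript length, with 65 the highest of 1000 permutations. The permutations held only transcript length fixed. The overlap of 148 is what a response of the cells to the drugs may give, but deeper libraries or other gene properties common to both kinds of cell could give it too. A response therefore remains a hypothesis found on the same data.

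Clustered protocadherins, adhesion genes on chromosome 5 at 140966235 to 141512981, were higher in DPF3 cells, with 16 of 25 called higher and 1 lower without drugs and 13 and 1 with drugs (adjusted p = 0.361 and 0.364 with an estimated correlation). Reads shared between paralogs were argued against for the 8 members with at least 80% of 50-base words of their own (median 0.52, 95% interval 0.48 to 0.81), and stay open for the 17 others (median 0.36). The 80% bound was chosen after the shares and folds were seen, since 1 member reached the 90% first set. An extra copy of the region was argued against by the 31 other genes within 1 Mb (median -0.0599, 95% interval -0.25 to 0.01). Both intervals come from resampling genes as if they were independent, so they leave out the spread between libraries. Whether DPF3 or another difference between the populations may be the source cannot be told apart, although 11 members were called higher both without and with drugs.

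G2 and M phase genes, which drive mitosis, were higher as a list in DPF3 cells without drugs, with 52 of 52 above 0 and an adjusted p = 0.554 with an estimated correlation. Called were 7, against 24 with the replicate block and 47 with the block and only the 2 groups. The same-numbered libraries differed by 0.65 to 0.77 in the mean log2 value. Scaling was argued against by a median of 0.68 after quantile normalization, against 0.70 on the values as deposited. With drugs the mean paired difference was -0.0614. Whether the density or growth of the populations, rather than DPF3, may explain the difference without drugs cannot be told apart, since nothing states that each plasmid was introduced more than once.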

How the results depend on the processing

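The common-sum scaling, the block with only the 2 groups and the block with an estimated correlation were chosen after seeing the data, and the other alternatives were planned. No called pair of a named gene and a comparison, and no called list, changed its sign. In the totals, the direction that held more of the calls turned round in each comparison under some alternative. Median-ratio scaling gave 4468 higher and 4178 lower for the drugs in empty-plasmid cells, and 4403 and 4164 in DPF3 cells. Quantile normalization gave 904 and 912 for DPF3 without drugs and 1300 and 1217 for DPF3 with drugs. A mean of at least 5 FPKM gave 205 and 196 for the interaction. How many single genes outside the named ones changed sign was not counted. Of 177 pairs of a named gene and a comparison, 168 were called, 152 of these kept the call and sign under every alternative run for them, 16 lost the call under at least 1 (3 of them only with 1 library left out), and 5 uncalled pairs were called under at least 1. Not every alternative was run for every pair, since filters left out some genes and only 2 groups give no interaction. The cause of the changes below was not tested, except that fewer genes or samples enter where the alternative removes them.

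The counts for the drugs stayed within 1.5 times, at 6544 to 11574 in empty-plasmid cells and 6417 to 10375 in DPF3 cells over the alternatives, and at 8697 to 9509 and 8719 to 9336 with 1 library left out. Array weights gave 3290 genes for DPF3 without drugs, 3496 for DPF3 with drugs and 1872 for the interaction. A mean of at least 5 FPKM gave 1405 for DPF3 with drugs and 401 for the interaction. With only the 2 groups compared DPF3 without drugs gave 1232 genes, and 2969 with the replicate block. The replicate block gave 1235 for the interaction, 2465 for DPF3 without drugs, 2780 for DPF3 with drugs, and 9716 and 9579 for the drugs in empty-plasmid and DPF3 cells. These last 2 comparisons were not treated as paired, although their same-numbered libraries had correlations above 0 (0.0832 to 0.195 and 0.0176 to 0.271). Apart from the lists given with it, the block in the fit of all groups changed no other call of a list by the preset correlation. Printed counts near 0 could move by over 1.5 times with it. For the drugs in empty-plasmid cells, 1 mitochondrial ribosomal protein was higher without the block and 2 with it. The interaction cannot be fitted with only 2 groups.

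With 1 library left out the counts were 972 to 2595 for DPF3 without drugs, 1196 to 2337 for DPF3 with drugs and 364 to 1365 for the interaction. The lowest were without DPF3 replicate 1 without drugs (972), and without empty-plasmid replicate 3 with drugs (1196 and 364), and the highest interaction count was without DPF3 replicate 3 without drugs (1365).

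The share of drug-called genes with the same sign in both kinds of cell was 95.5% after quantile normalization and 94.8% to 97.0% with 1 library left out. The correlation of the averaged effects was -0.0112 at a mean of at least 5 FPKM, -0.155 with a pseudocount of 0.1 and -0.122 to -0.0552 with 1 library left out.

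With an estimated correlation 2 lists were called for the drugs in empty-plasmid cells, 1 for the drugs in DPF3 cells, and 0 for DPF3 without drugs, DPF3 with drugs and the interaction. With the block and an estimated correlation these were 2, 2, 0, 0 and 0, as astrocyte markers in DPF3 cells with the drugs passed (adjusted p = 0.0483, against 0.0542 without the block). Limma's fry, which asks whether a list moves and does not compare it with other genes, called 32, 26 and 12 lists for the drugs in empty-plasmid cells, the drugs in DPF3 cells and DPF3 with drugs. Quantile normalization called 1 list for DPF3 with drugs and 7 for the interaction. The depth is unknown, so low values carry a counting error that cannot be given.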

Other observations

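The gene families here and both tests below were chosen after the values were seen. None of the 6 families in this paragraph kept a call with an estimated correlation for the drugs in either kind of cell (adjusted p = 0.151 to 0.522). The counts below are for the drugs in empty-plasmid cells. Of 46 proteasome subunits 42 were lower and 1 higher, with the immunoproteasome subunit PSMB10 going from 84.9 ± 7.76 to 4.03 ± 0.407 FPKM (SD, n = 3 each, limma log2 fold change -4.09). Of 21 genes of MHC class I presentation 17 were lower and 1 higher. All 20 cytosolic aminoacyl-tRNA synthetases were lower, such as WARS, which charges tryptophan (218 ± 38.9 to 32.5 ± 5.53 FPKM). Of 78 mitochondrial ribosomal proteins 63 were lower and 1 higher, and after quantile normalization 42 were lower and 7 higher. Histone genes of the HIST clusters had 23 of 30 higher and none lower, such as HIST2H4A (2.29 ± 0.323 to 16 ± 1.45 FPKM), which has an identical copy that reads cannot be told from, and metallothioneins, which bind zinc and copper, had 7 of 8 higher and 1 lower. In DPF3 cells the numbers higher and lower were 1 and 42, 1 and 17, 0 and 20, 2 and 55, 19 and 2, and 6 and 0 in the same order. Poly(A) selection under-represents most replication-dependent histone mRNAs, so the histone counts may reflect only RNA with a poly(A) tail and not total histone RNA.

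DPF3 RNA was 2.89-fold higher with drugs in DPF3 cells, and effects that grow with it could give larger DPF3 effects with drugs. The slope of the effect with drugs on that without was 1.02 over 3276 genes. These genes were chosen for the average of the 2 effects, which draws the slope to 1, so it decides nothing, and whether the effects grow with the level stays open.

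A whole autosome gained or lost in one population could shift all of its genes. The autosome median farthest from 0 for DPF3 without drugs was 0.0378, and the 22 autosome medians lay between -0.01 and 0.04, which argues against it for autosomes. Chromosome X was not examined.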
